A study of Mus musculus with 19 samples.

How the data were processed

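Lung dendritic cells (DC) of C57BL/6 mice were measured in 19 samples. For 4 conditions, wild-type (WT) and Ccr7 knockout (KO) mice with or without tumors of KP cells, 1 library of RNA and 1 library of surface protein tags were made from the same single cells. The other 11 samples are bulk RNA of sorted lung cDC1: bead-negative (3), bead-positive (3), GFP-negative (2) and GFP-positive (3). Per the labels' protocols the single cells were sorted as CD45+ Siglec F- Ly6G- MHCII+ CD11c+, and the cDC1 additionally by CD24, CD11b and CD103.

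The authors deposited UMI counts per gene and cell for RNA and counts of 5 antibody tags per cell; the values are whole numbers with no normalization. The submitters' processing notes name Cell Ranger 2.1 and STAR 2.5 and the builds mm10 and GRCh38, without saying which build or tool served which file, and no annotation is named. The authors' cell table, per the file headers, gives a quality flag, a score, a cluster number and a cluster name for each barcode. Of 11899 barcodes, 10025 carried the passing flag: 2099 in WT naive, 2653 in WT tumor, 2694 in KO naive and 2579 in KO tumor. Tested on the files, the lowest UMI count among passed cells was 802 to 811 per library and the highest mitochondrial share 21.7 to 24.9%. The authors' 5 annotated clusters were used as they stand: DC1, DC2, mregDC (called mature DC here) and 2 clusters annotated together as macrophages and contaminants.

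The bulk files hold a linear signal per gene, deposited after a gene filter that left 9626 genes in the bead libraries and 11574 in the GFP libraries. How these values were made is not recorded in the labels, so it was worked out from the values. In the bead libraries, 9625 of 9626 genes lay within 0.02 of a whole read when the signal was divided by 1 step per library and a small fixed offset was taken off; the exception was March2. Bead values are thus reads scaled by library, and were tested as deposited. In the GFP libraries each signal value was taken to have been divided in addition by a number that belongs to another row. This is inferred from the values, and no label or header records it. In that reading the divisor has the length of the gene list and runs across the rows of an 11-column table, so that the 5 libraries of 1 gene carry 5 unrelated divisors. Removing it gave values within 0.00355 of a whole read for all 11574 genes in all 5 libraries. The same search still gave whole reads for 37.7% of sets with the rows of 1 library shuffled, so whole reads alone do not show that the divisor is right. For 56 divisors (0.484%) the set of reads shared a factor, which leaves their scale open. As deposited, the GFP libraries correlated at 0.516 to 0.547 across genes and the median SD between libraries was 2.17 on the log2 scale. After the divisor was removed, the correlations were 0.958 to 0.983 and the median SD was 0.197, near the 0.231 of the bead libraries. The reads were then turned into CPM with an effective size for each library, on the same scale as the bead values. These sizes came from the steps between libraries, which were worked out from the deposited values. The read-based values are used for the GFP libraries throughout. This choice was made after the data were examined. It used no group label, and the values as deposited were kept as an alternative.

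In M reads, the listed genes held 3.17, 48.6 and 16.0 in bead-negative replicates 1 to 3, 14.3, 10.7 and 10.4 in bead-positive replicates 1 to 3, 29.0 and 44.4 in GFP-negative replicates 1 and 2, and 32.9, 39.0 and 22.8 in GFP-positive replicates 1 to 3. The labels do not say whether replicates are separate animals, so every p-value measures the spread between these samples. Since the files hold a normalized signal, bulk comparisons used limma 3.58.1 on log2 values with 1 added (lmFit, eBayes with a trend of variance with mean, 2-sided moderated t-test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; the plan had named edgeR for the case of counts and limma for normalized values. The bead fit used 6 libraries and the GFP fit 5. The difference of the 2 effects was tested in 1 fit of all 11 libraries with a mean for each group, on the 9516 genes listed in both. No filter was applied beyond the authors' own gene lists.

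Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01 on the same log2 values, in place of the planned log2 CPM of counts. The 35 lists of pathways, lineages and other cell types were written before the data were examined; 3 more, of 100 genes each, came from the single cells as the genes highest in mature DC over DC1, DC1 over mature DC and DC2 over DC1. Adjustment was by Benjamini-Hochberg over the lists with measured members. Lists named as study lists hold genes recalled from the study's own account, and the list of mreg markers shares many of them.

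Replicate numbers were checked for pairing by the correlation of deviations from the group means. In the bead libraries the same-numbered pairs correlated at 0.269, 0.302 and 0.391, each above 0.1, and the other pairs at -0.302 to -0.0746. Deviations in a group of 3 sum to 0, so these values depend on each other and the check is weak. The pairing is read from the data alone, and the fit with the number as a block was kept as an alternative. The GFP libraries have only 2 pairs, too few to decide.

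Single-cell counts of passed cells were summed per library and class and divided by the total, as CPM, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Intervals are exact 95% Poisson intervals for CPM and exact 95% binomial (Clopper-Pearson) intervals for shares; they carry counting error only. With 1 library per condition nothing was tested between conditions. Ratios are log2 with 10 CPM added. A gene at 0 counts in 1 library is given a floor of 3 counts there. List medians were placed as percentiles among 10000 random lists matched on mean expression, over genes at 50 CPM or more in 1 library of the pair. Tags were turned into centred log-ratios per cell, averaged per class and library, and compared over the 4 libraries with an exact 2-sided sign-flip test, whose smallest possible p is 0.125, adjusted by Benjamini-Hochberg over tags and pairs of classes. Figures were drawn with matplotlib 3.10.9.

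Genes were named by a rule fixed before the data were examined. In bulk these are the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with a mean log2 value of 4 or more and no overlap between groups, a fixed set of 12 genes, and up to 4 members of each list with the smallest p. In single cells they are the 10 highest and 10 lowest ratios per class among genes at 50 CPM or more in 1 library of the first pair, with a ratio of the same sign and at least 0.58 in size in the second pair. Other genes printed were chosen after their values were seen and are said to be.

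The scripts were tested on simulated data. In simulated bead libraries limma recovered 95 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2. In simulated GFP libraries it recovered 42 and 100, and for the difference 58 and 98. These simulations gave all genes 1 common dispersion and drew changed genes from those with more reads, so they lack the spread of single genes. The step that turns GFP values into reads recovered every read count exactly for 99.8% of 11574 simulated genes. For the single-cell lists, 10 of 10 lists with doubled genes were found and 4 of 50 unchanged lists lay beyond the outer 2.5% of random lists on either side. For camera, 10 of 10 risen lists and 0 of 50 unchanged lists were called.

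Alternatives tried for the bulk results were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, DESeq2 size factors, pseudocounts of 0.1 and 5, a minimum mean value of 5, the replicate block, 1 fit of all 11 libraries, each library left out in turn, and for GFP the values as deposited. Lists were also run with an estimated correlation, with fry, and with a prior count of 2. Single cells were rerun with 1 CPM added, a 20 CPM minimum, TMM factors, doublets called by Scrublet (scanpy 1.11.5) left out, a minimum of 1000 UMIs, and cells thinned to 1000 UMIs. Left out were the 1874 barcodes without the passing flag, and any gene the authors' bulk lists do not hold. The planned run without a filter on low counts could not be made, since the deposited lists were already filtered.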

Results

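Lung DC of naive mice and of mice carrying KP lung tumors (Kras activated, Tp53 deleted), with and without Ccr7, were measured by RNA and 5 surface tags in single cells. Sorted cDC1 that had or had not taken up beads or tumor GFP were measured in bulk. The single-cell part holds 1 library per condition. WT naive gave 2099 passed cells and 13163598 UMIs, WT tumor 2653 and 20930148, Ccr7 KO naive 2694 and 12561428, and Ccr7 KO tumor 2579 and 16619650. Median UMIs per cell were 6104, 7556, 4518 and 6251 in that order, and median tag counts 3588, 4071, 1621 and 2052. The bulk part holds cDC1 without (3) or with (3) ovalbumin-coated beads 5 h after they were given through the nose, and cDC1 without (2) or with (3) GFP from GFP-expressing KP tumors at day 28. Reads over listed genes ran from 3.17 M in bead-negative replicate 1 to 48.6 M in bead-negative replicate 2, and from 22.8 M in GFP-positive replicate 3 to 44.4 M in GFP-negative replicate 2, as worked out from the deposited values.

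The knocked-out gene was read first. Ccr7, the receptor that guides mature DC to lymph nodes, stood at 1703 CPM (95% interval 1602–1808) in mature DC of WT naive mice and 1997 (1935–2061) of WT tumor mice. In the KO libraries it stood at 565 (510–625) without and 411 (372–453) with a tumor, log2 ratios of -1.57 and -2.25. Mature DC with a Ccr7 UMI were 88.0% in WT naive, 92.4% in WT tumor, 70.9% in KO naive and 72.6% in KO tumor. Among macrophages and contaminants, which should lack the receptor, the shares were 3.98, 7.93, 2.40 and 6.29%, at median depths of 4005, 7397, 2724.5 and 6576.5 UMIs against 5629, 5840, 3754 and 4658.5 in mature DC. With every cell thinned to 1000 UMIs, mature DC with a Ccr7 UMI were 67.0, 72.8, 46.5 and 35.6%. Ccr7 RNA was thus lower in both KO libraries but far from absent. The deleted part may lie outside the counted 3' end, so the remaining UMIs check little about the protein. Intervals here and below carry counting error only, and with 1 library per condition no difference between conditions was tested.

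How the make-up of lung DC differs with a tumor and without Ccr7 was asked of the authors' classes, in cells gated on MHCII and CD11c. Mature DC, marked by Fscn1, Ccl5, Ccr7, Il12b and Ccl22, were 6.79% (95% interval 5.65–8.09) of DC in WT naive and 21.6% (19.5–23.8) in WT tumor. In KO they were 8.14% (7.04–9.35) without and 12.9% (11.3–14.6) with a tumor. DC1, marked by Xcr1, Tlr3 and Clec9a, were 56.7% (54.3–59.0) and 27.0% (24.8–29.4) in WT naive and tumor, and 61.0% (59.0–63.1) and 35.2% (32.9–37.6) in KO. DC2, marked by Cd209a, Ifitm1 and Clec10a, were 36.5% (34.2–38.9) and 51.4% (48.8–53.9) in WT, and 30.8% (28.9–32.8) and 51.9% (49.4–54.3) in KO. Among DC, both tumor libraries thus held larger shares of mature DC and DC2 and smaller ones of DC1 than their naive counterparts, and the mature share with a tumor was higher in WT than in KO. Of all annotated cells, DC2 were 29.97% in WT naive and 28.4% in WT tumor, the opposite direction, and 25.6 and 33.0% in KO. Macrophages and contaminants in the same gate were 18.0% of annotated cells in WT naive, 44.7% in WT tumor, 17.0% in KO naive and 36.4% in KO tumor. One of their clusters, marked by Gpnmb, Ctsd and Spp1, counted 13, 508, 14 and 286 cells in the 4 libraries, and the other, marked by Retnla, Ccl24 and Arg1, 364, 677, 444 and 652. Clusters were drawn by the authors over all 4 libraries at once, and shares of 1 class move the others.

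**Figure D1:**
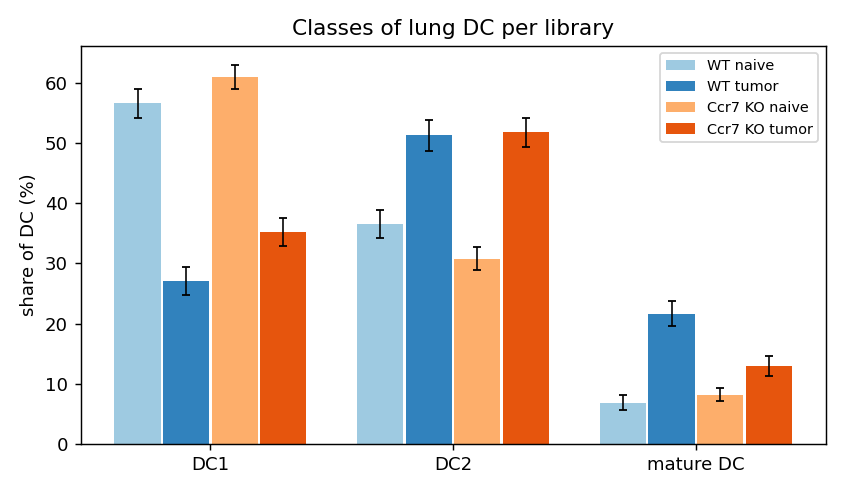
Share of DC1, DC2 and mature DC among DC in each of the 4 libraries, with exact 95% binomial intervals. Mature DC stood at 6.79% in WT naive, 21.6% in WT tumor, 8.14% in Ccr7 KO naive and 12.9% in Ccr7 KO tumor, while DC1 stood at 56.7, 27.0, 61.0 and 35.2%.

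Within DC1, the tumor libraries differed from the naive ones most in Plet1, a GPI-anchored surface protein, at 18.9 CPM (15.8–22.4) in WT naive and 532 (508–556) in WT tumor, and 42.3 (37.8–47.2) and 456 (435–478) in KO. Cxcl9, the T cell attracting chemokine, read 10.1 CPM (7.89–12.7) and 97.4 (87.4–108) in WT and 23.3 and 50.9 (44.0–58.5) in KO. Higher with a tumor in both genotypes were also Ctsd (log2 2.76 in WT, 1.75 in KO), Tm4sf5 (2.66, 1.85), Fabp5 (2.11, 1.46) and Serpina3g (1.99, 1.44). So were Ifitm2 (1.98, 1.62), Mfge8 (1.87, 0.73), Serpinb6b (1.84, 1.32) and Isg15 (1.69, 0.91). Ctsd, Fabp5 and Mfge8 are also macrophage genes, and in DC1 of the WT tumor library they reached 2.84, 3.23 and 41.7% of the macrophage level. Lower with a tumor were Pdlim1 (-1.98 in WT, -2.15 in KO), the leukotriene receptor Ltb4r1 (-1.83, -2.27), Clec4b1 (-1.76, -1.02) and S100a10 (-1.63, -1.69). Also lower were Cfh (-1.53, -1.49), Dusp2 (-1.52, -0.88), Trf (-1.48, -1.54), Ahnak (-1.48, -1.24) and Nr4a1 (-1.46, -1.37). The surfactant gene Sftpc, made by alveolar epithelium, read 248 CPM (236–260) in DC1 of WT naive and 6.47, 10.1 and 3.10 in WT tumor, KO naive and KO tumor, so its ratio follows 1 library. The lineage genes Xcr1 (0.35, 0.41) and Clec9a (0.20, 0.06) differed little. Pdcd1lg2, which encodes PD-L2, had no UMI in DC1 of WT naive and 13.2 CPM (9.72–17.6) in WT tumor, at least 31-fold higher. In KO it read 0.532 (0.145–1.36) and 9.04 (6.29–12.6). Cd274 stood at 1.28 and 9.85 CPM in WT and 0.399 and 4.13 in KO, and Ccr7 at 4.84, 11.3, 4.66 and 3.10 CPM in the 4 libraries.

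Within DC2, the largest differences were in Ifitm1, an interferon-inducible membrane protein, at 15.8 CPM (12.1–20.3) in WT naive and 1304 in WT tumor. In KO it read 63.0 (54.4–72.7) and 1297 (log2 5.67 and 4.16). Plet1 read 11.7 CPM (8.51–15.6) and 486 (469–504) in WT and 21 (16.1–26.9) and 763 (741–787) in KO. Clec4n, a fungal pattern receptor, read 49.8 (43.0–57.4) and 433 (417–450) against 52.0 (44.2–60.9) and 699 (678–722). Higher as well were Fabp5 (log2 3.0 in WT, 1.47 in KO), the decoy receptor Il1r2 (2.64, 2.56), Cd63 (2.57, 1.47), AA467197 (2.49, 1.81), Serpina3g (2.41, 1.11), Cxcl9 (2.29, 1.39) and Itgae (2.24, 2.01). The metallothionein Mt2 was lower (-2.51, -2.69), as were Lmna (-2.39, -1.69), Pdlim1 (-2.25, -2.20), Hpgd (-2.22, -1.93) and Fcrls (-2.16, -2.03). Also lower were Skint3 (-1.96, -1.88), Clec4b1 (-1.88, -1.76), Trf (-1.87, -2.19), Adgre1 (-1.81, -1.76) and Sepp1 (-1.73, -1.86). Among immune checkpoint and costimulation genes, Pdcd1lg2 (2.02, 1.87), Cd274 (1.45, 1.24), Il4ra (1.11, 0.76) and Cd86 (0.71, 0.90) were higher with a tumor in both genotypes, and Ccr7 more so in WT (1.72) than in KO (0.60).

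Within mature DC, Il12b, the subunit of the T cell activating cytokine IL-12, stood lower with a tumor, at 750 CPM (684–821) in WT naive and 289 (266–314) in WT tumor, and 944 and 482 (440–527) in KO. The make-up of the class differed too. Cells with DC1-like PE and CD11b tags were 62.4% of mature DC in WT naive and 25.6% in WT tumor, and 60.4 and 17.9% in KO. Among these cells the log2 ratio of Il12b was -0.84 in WT and 0.49 in KO, and among the DC2-like cells 1.58 (11 UMIs in WT naive) and -0.54. The PD-1 ligands stood higher. Pdcd1lg2 read 31.7 CPM (19.4–49.0) and 139 (123–156) in WT and 75.3 (56.0–98.9) and 199 (172–228) in KO. Cd274 read 53.9 (37.3–75.3) and 134 (118–151) in WT and 66.4 (48.4–88.8) and 98.8 in KO. Il1b read 82.4 CPM (61.6–108) and 502 (472–535) in WT and 236 (201–276) and 663 (613–715) in KO. Other genes higher in both genotypes were Tcf7 (log2 2.40 in WT, 0.69 in KO), Isg15 (2.30, 0.66), Il1rn (2.06, 0.99), Plscr1 (1.85, 1.05), Ptpn1 (1.78, 1.32) and Got1 (1.77, 0.60). Clec4n had no UMI in WT naive and 101 CPM (87.8–117) in WT tumor, at least 21.3-fold higher, with 2.95 (0.357–10.7) and 164 in KO. Ifitm1 read 3.17 (0.384–11.5) and 230 (210–253) in WT and 93.0 (71.4–119) and 394 (356–435) in KO. Lower were Pdlim1 (-2.32, -1.30), Lmna (-2.14, -2.04), Ahnak (-2.11, -1.15), Cd36 (-2.06, -1.29) and Klf2 (-1.95, -2.54). The same held for Cdkn2a (-1.92, -1.51), Sgms1 (-1.83, -1.50), Tnni2 (-1.73, -1.31), Itgb8 (-1.71, -1.12) and Cd44 (-1.64, -1.30). Cd200 and Cd80 went opposite ways, higher with a tumor in WT (0.98 and 0.84) and lower in KO (-0.52 and -0.25).

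Type I interferon response genes had medians above 0 with a tumor in every class, except that in mature DC of KO the median was -0.013 at a 20 CPM minimum. The gap between WT and KO was not tested, and the KO medians lay within the range of random lists. The median log2 ratio was 0.79 in DC1 of WT (6 of 6 genes above 0, percentile 99.98 among 10000 random lists) and 0.24 in KO (4 of 5, 92.8). It was 1.23 in DC2 of WT (6 of 6, above all; 0.71 at a 20 CPM minimum) and 0.24 in KO (4 of 5, 77.9), and 0.62 in mature DC of WT (7 of 8, 99.94) and 0.31 in KO (5 of 7, 93.0). Immediate early genes, which respond to tissue dissociation as well as to signals in the animal, stood lower in every class. Their medians were -0.98 (0 of 18 above 0) and -0.95 (0 of 16) in DC1 of WT and KO, -0.92 (0 of 21) and -0.96 (0 of 19) in DC2, and -0.45 (2 of 13) and -0.84 (1 of 13; -0.51 at a 20 CPM minimum) in mature DC. Interferon gamma response genes were higher in DC2, at 0.77 in WT (11 of 11) and 0.41 in KO (10 of 10). In mature DC they stood at 0.67 (11 of 13) in WT and 0.18 (10 of 13) in KO. Glycolysis and hypoxia genes were higher in DC2, 0.92 (12 of 12) in WT and 0.67 (10 of 10) in KO, and genes of MHC class I and cross-presentation in DC1, 0.39 (14 of 16) and 0.20 (14 of 16). Cholesterol synthesis genes were lower in mature DC, -0.79 (2 of 12 above 0) in WT and -0.60 (1 of 13) in KO, and cDC2 markers lower in DC2, -0.51 (4 of 12) and -0.43 (3 of 12). The immunoregulatory study list had a median of 0.98 (5 of 7 above 0) in mature DC of WT and -0.17 (2 of 6) of KO. mreg markers had a median of 0.76 (9 of 10) in DC2 of WT and -0.20 (3 of 8) of KO, the latter turning to 0.22 at a 20 CPM minimum. The members measured differ between the genotypes, and no difference between genotypes was tested. Both hold genes the study picked, so neither is independent evidence. These lists were picked for print after all list values had been seen.

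What the loss of Ccr7 does inside a class was read from KO over WT, without and with a tumor. In DC2 the sharpest difference was BC018473, a non-coding transcript, with no UMI in either WT library and 215 CPM (199–232) and 174 (163–185) in KO naive and KO tumor, at least 277-fold and 365-fold higher. St6galnac2, a sialyltransferase, read 0.259 CPM (0.00657–1.44) and 0.159 (0.00402–0.884) in WT naive and tumor, 1 UMI each, against 59.0 (50.7–68.4) and 66.3 (59.7–73.4) in KO. In mature DC, BC018473 was at 56.1 CPM (39.7–77.0) and 32.9 (22.7–46.3) in KO and 0 in WT. Sphk1, a lipid kinase, was at 59.0 (42.2–80.4) and 26.9 (17.8–39.2) in KO against 3.17 (0.384–11.5) and 7.13 in WT. The neutrophil gene S100a8 was lower in mature DC of KO (log2 -3.32 naive, -2.17 tumor), as were S100a9 (-2.26, -0.73), Csf2ra (-1.58, -0.68), H2-Q4 (-1.32, -1.23), Nsf (-1.27, -0.62), Rpl9 (-1.16, -0.80) and Gm10020 (-1.13, -1.03). Higher there were Prnp (1.64, 0.64), Lgmn (1.11, 0.59), Crem (1.1, 0.62), Plek2 (1.04, 0.78), S100a10 (1.01, 0.61), Timd4 (0.94, 1.19), Pkib (0.91, 0.61) and Ifitm1 (2.97, 0.75). Of the fixed genes in mature DC, Pdcd1lg2 (1.03, 0.49), Cd86 (0.75, 0.72) and Il12b (0.33, 0.72) were higher in KO in both states, while Cd80 (1.41, 0.33) and Cd200 (1.41, -0.09) differed mainly without a tumor.

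Single ribosomal protein genes were among the lowest ratios of KO over WT in each class, although as a group they went both ways. Of those measured, 47 of 88 in DC1 and 47 of 90 in DC2 were lower in both KO libraries. The medians were -0.11 without and -0.14 with a tumor in DC1, and -0.025 and -0.17 in DC2. Rpl35 was lower in DC1 (log2 -1.36 naive, -1.19 tumor) and in DC2 (-1.35, -1.13), and so were Rpl23a (-1.39, -1.05 and -1.31, -1.05), Rpl38 (-1.05, -1.07 and -1.01, -1.08) and Rpl41 (-1.06, -0.99 and -1.03, -0.97). In mature DC, Rpl23a (-1.91, -1.29) and Rpl35 (-1.32, -0.92) were lower too. DC1 also had less Gm9844 (-1.20, -1.0), Rps27 (-1.19, -0.71), Tmsb10 (-1.08, -1.06), mt-Nd3 (-1.05, -1.25), Rpl37 (-1.02, -0.97) and Fmnl1 (-1.02, -0.66). DC2 had less Hpgd (-1.25, -0.96), Mt1 (-1.15, -0.80), Mt2 (-1.11, -1.29), Rps28 (-1.08, -1.06), Mettl23 (-1.04, -1.03) and Gm10073 (-1.02, -0.79). The langerin gene Cd207 was higher in DC1 of KO (0.82, 0.76), with Bst1 (0.53, 0.61), Tk1 (0.49, 0.59), Epcam (0.47, 0.59), Dynll1 (0.31, 0.59) and F2rl2 (0.31, 0.72). In DC2, Epcam (0.67, 0.79), Rrm2 (0.44, 0.60), Cdk1 (0.42, 0.83), Tubb4b (0.31, 0.70), Birc5 (0.29, 0.80), Scimp (0.26, 0.58), Tk1 (0.24, 0.71) and Cks1b (0.24, 0.63) were higher in KO. Cell cycle genes as a list stood at a median of 0.11 in DC2 without a tumor (14 of 16 above 0) and 0.56 with one (19 of 19, above all random lists). In DC1 it stood at 0.16 (13 of 15, percentile 98.6) and 0.17 (13 of 19, 95.8). Immediate early genes, which respond to tissue dissociation, stood lower in KO. Their medians were -0.47 (1 of 18 above 0) without and -0.53 (0 of 12) with a tumor in DC1, and -0.40 (2 of 21) and -0.27 (2 of 19) in DC2, all 4 below every random list. In mature DC they were -0.16 (4 of 13, percentile 5.73; -0.081 with TMM factors) and -0.30 (3 of 10, 0.14). Genotype and library cannot be told apart, because each genotype has 1 library per state.

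Whether mature DC resemble DC1 or DC2 on their surface was asked with the 5 tags. The MHC class II tag (I.A.I.E) was highest on mature DC, 2.36 above DC1 (SD 0.228 over 4 libraries) and 1.06 above DC2 (SD 0.261) in centred log-ratio units, in 4 of 4 libraries. The CD11b tag lay between the classes, 1.5 above DC1 (SD 0.463) and 2.13 below DC2 (SD 0.963). So did the tags named PE, 2.46 below DC1 (SD 0.732) and 0.92 above DC2 (SD 0.521), and APC, 1.26 below DC1 (SD 0.249) and 0.81 above DC2 (SD 0.711). CD11c was 0.14 lower than on DC1 (-0.14, SD 0.253, higher in 1 of 4 libraries; exact sign-flip p = 0.375), with -0.042 without WT naive and -0.23 without KO tumor, and was 0.66 lower than on DC2 (SD 0.0176). Between DC1 and DC2, PE was higher on DC1 by 3.38, APC by 2.08, CD11b lower by 3.62, I.A.I.E lower by 1.3 and CD11c lower by 0.53. Every one of these but CD11c against DC1 went the same way in all 4 libraries, which gives the exact sign-flip test its smallest possible p (adjusted p = 0.134), so none passed. On log2 counts per 1000 tags, a different scale, CD11c was lower on mature DC than on DC1 in 4 of 4 libraries (-1.89). On that scale APC was higher on mature DC than on DC2 in 2 of 4 libraries and PE in 3 of 4, and CD11c was higher on DC1 than on DC2 in 2 of 4. Both scales are relative to the other tags of a cell, so a high I.A.I.E count lowers the others. Median CD11c counts were 255 on mature DC and 194 on DC2 in WT naive, and 127.5 and 109 in KO naive. They were 339 and 443 in WT tumor, and 228.5 and 318 in KO tumor. The files do not say what the tags named PE and APC bind.

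How cDC1 that took up an ovalbumin-coated bead differ from those that did not was asked by comparing bead-positive with bead-negative cells. Cells were parted by uptake itself, so an effect of uptake and a difference that came before it cannot be told apart. Rises and falls with beads, here and below, mean higher or lower in bead-positive than in bead-negative cells. Il12b rose from a mean of 49.8 (SD 12.3) to 1046 (SD 163), a log2 change of 4.38 (SE 0.17, limma, Benjamini-Hochberg adjusted p = 2.75e-07), and Lrrc32, which displays latent TGF-beta, rose from 12.7 (SD 2.95) to 208.8 (SD 66.4), by 3.92 (SE 0.21, adjusted p = 1.05e-06). The lipid desaturase Scd1 rose by 3.49 (SE 0.20, adjusted p = 1.24e-06) and the prostaglandin synthase Ptgs2 by 3.26 (SE 0.48, adjusted p = 0.000588). The interleukin-1 antagonist Il1rn rose by 3.22 (SE 0.19, adjusted p = 1.29e-06) and the neutrophil chemokine Cxcl2 by 3.06 (SE 0.26, adjusted p = 1.43e-05). Gem (3.17), Scin (3.13), Plaur (3.10) and Cd69 (3.01) completed the 10 largest rises. Neutrophil markers rose in the same samples (median 2.58), and neutrophils also express Il1rn, Cxcl2, Ptgs2 and Plaur. The largest falls were in Gm10800 (-2.83, SE 0.64, adjusted p = 0.00782), the chemokine receptor Cxcr3 (-1.88, SE 0.29, adjusted p = 0.000757), Rnf144b (-1.38), Tifab (-1.36) and Itga8 (-1.36). Rtl8c (-1.34) and Unc119 (-1.31) fell too, with the innate sensors Tlr11 (-1.26, SE 0.14, adjusted p = 7.82e-05) and Tlr3 (-1.23, SE 0.13, adjusted p = 7.64e-05), and Ptpn18 (-1.24). In all, 2835 of 9626 genes changed (29.5%), 1613 up and 1222 down, by limma. The falls numbered 792 and 738 without bead-negative replicates 1 and 2, and 1838 with the replicate number as a block. edgeR gave 2826 and DESeq2 2837. At an unadjusted p under 0.05 there were 3937 against 481.3 expected by chance, and in 45.4% of genes the groups did not overlap, against 10% by chance for 3 against 3.

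The fixed genes of maturation and checkpoint function rose with beads. Cd274, which encodes PD-L1, rose from 47.3 (SD 5.22) to 334 (SD 36.7), by 2.79 (SE 0.11, limma adjusted p = 3.29e-07). Pdcd1lg2 rose by 2.47 (SE 0.13, adjusted p = 9.96e-07) and Ccr7 from 387 (SD 62.2) to 1395 (SD 179), by 1.85 (SE 0.13, adjusted p = 4.79e-06). Cd80 rose by 2.32 (SE 0.12, adjusted p = 1.04e-06), Cd40 by 1.73 (SE 0.15, adjusted p = 1.61e-05) and Cd86 by 1.15 (SE 0.10, adjusted p = 1.78e-05), with Axl, a receptor for dying cells, at 1.49 (SE 0.24, adjusted p = 0.00104). Il4ra rose by 0.70 (SE 0.13, adjusted p = 0.00239) and Cd200 by 0.39 (SE 0.10, adjusted p = 0.0148). The lineage genes Clec9a (-0.65, SE 0.09, adjusted p = 0.000462) and Xcr1 (-0.43, SE 0.09, adjusted p = 0.00523) fell.

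**Figure D2:**
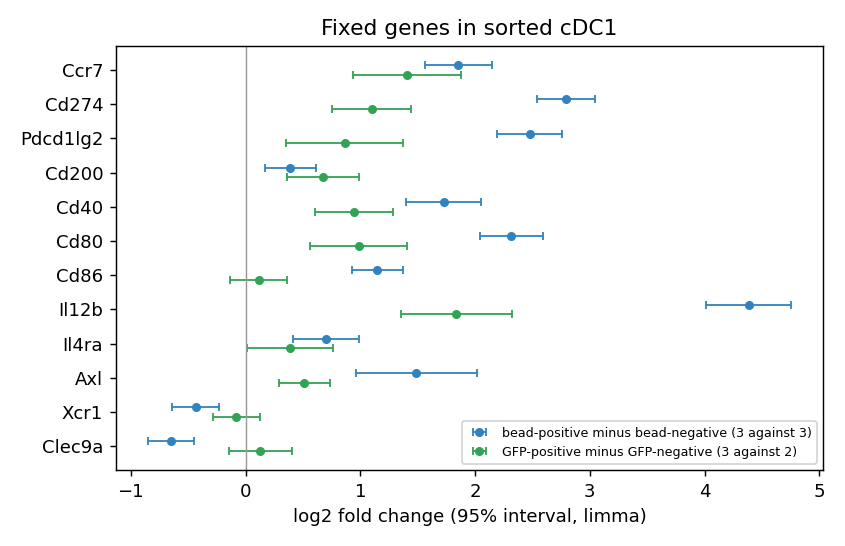
Log2 change of the 12 fixed genes with bead uptake (blue) and GFP uptake (green), with 95% intervals from limma. Il12b stood at 4.38 with beads and 1.84 with GFP, Cd274 at 2.79 and 1.1, Ccr7 at 1.85 and 1.41, and Clec9a at -0.65 and 0.13.

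As gene groups, the mature DC program rose and the DC1 program fell with beads. Of the 83 measured genes that were highest in mature DC over DC1 in the single cells, 73 rose and 0 fell (median log2 1.51), with Nr4a3 at 2.90 and Rgs1 at 2.61 (camera adjusted p = 4.58e-35; adjusted p = 0.195 with an estimated correlation). Of the 86 in the DC1 list, 65 fell and 3 rose (median -0.61), among them Unc119, Il16 at -1.19 and Anxa6 at -0.95 (adjusted p = 5.29e-17; adjusted p = 0.195 with an estimated correlation). cDC1 markers fell in 9 of 13 (median -0.61), with the lineage factor Irf8 down by 1.02 on the log2 scale (-1.02, SE 0.13, adjusted p = 0.000251) and Naaa at -0.89 (camera adjusted p = 8.49e-05; adjusted p = 0.195 with an estimated correlation). The DC2 list rose in 49 of 85 and fell in 3 (median 0.86; 0.46 with lists of 200 genes), with Gadd45b at 2.32, Nfkbiz at 2.08 and Il1b at 1.78 (adjusted p = 1.38e-11; adjusted p = 0.195 with an estimated correlation). Gadd45b is also in the mature DC list, as are other DC2 list members such as Il4i1 and Ccl17, so these lists overlap. cDC2 markers rose in 7 of 12, including Cebpb at 2.30, Zeb2 at 1.97 and Irf4 at 1.6 (adjusted p = 0.00385; adjusted p = 0.320 with an estimated correlation). mreg markers rose in 16 of 17 (median 1.51; adjusted p = 5.29e-12; adjusted p = 0.195 with an estimated correlation). The study lists, which hold genes the study picked and so are not independent evidence, rose in 7 of 7 maturation genes (adjusted p = 1.34e-08) and 6 of 6 immunoregulatory genes (adjusted p = 5.23e-06). They rose in 8 of 8 migration genes (adjusted p = 1.91e-06) and 6 of 6 Th2 response genes (adjusted p = 5.46e-05). With an estimated correlation these 4 had adjusted p = 0.195, 0.195, 0.195 and 0.197. TLRs and adaptors fell in 4 of 11 and rose in 1 (median -0.17; adjusted p = 0.0739), and passed with the replicate number as a block (adjusted p = 0.0478) and by fry (adjusted p = 0.0131).

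Inflammatory signaling rose with beads. NF-kB targets rose in 17 of 18 (median 1.40), with Rel at 1.86 and Tnfaip3 at 1.6 (camera adjusted p = 4.27e-14; adjusted p = 0.195 with an estimated correlation). Type I interferon response genes rose in 20 of 24 (median 1.34), including Rsad2 at 2.56, Oasl1 at 2.5 and Ifit2 at 1.83 (adjusted p = 8.90e-13; adjusted p = 0.197 with an estimated correlation). Interferon gamma response genes rose in 12 of 20 and fell in 4, with Cxcl10 at 1.73 and Irf1 at 0.69 (median 0.62; adjusted p = 0.000392; adjusted p = 0.195 with an estimated correlation). T cell recruiting and stimulating cytokines rose in 10 of 14 and fell in 1, with Ccl22 at 2.69 and Cxcl16 at 1.26 (median 1.34; adjusted p = 7.81e-06; adjusted p = 0.195 with an estimated correlation). Immediate early genes rose in 8 of 21 and fell in 1, Ier3 at 1.69 and Klf2 at -0.75 (adjusted p = 0.0365; adjusted p = 0.572 with an estimated correlation and 0.159 by fry). Neutrophil markers rose in 9 of 9, among them S100a8 at 2.58 (SE 0.60, adjusted p = 0.00836), Csf3r at 2.80 and Lcn2 at 1.93 (median 2.58; camera adjusted p = 0.000523; adjusted p = 0.369 with an estimated correlation and 0.0693 by fry), although Ly6G-positive cells had been gated out. The rises of Il1b, Cxcl2, Il1rn and Plaur came in the same samples.

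Metabolic and stress genes moved as well. LXR targets and cholesterol efflux genes rose in 6 of 10, with Mylip at 1.32 and Abcg1 at 0.91 beside Scd1 (camera adjusted p = 0.000636; adjusted p = 0.214 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 19, with Ldlr at 1.46 and Hmgcs1 at 0.95 (adjusted p = 0.00317; adjusted p = 0.215 with an estimated correlation). Oxidative stress genes and metallothioneins rose in 9 of 13, with Gclc at 1.83, Sqstm1 at 1.81 and Srxn1 at 1.72 (adjusted p = 3.73e-05; adjusted p = 0.215 with an estimated correlation). Unfolded protein response genes rose in 6 of 12, with Trib3 at 1.49 and Ddit3 at 1.34 (adjusted p = 0.00816; adjusted p = 0.349 with an estimated correlation). Lysosome and phagosome genes rose in 15 of 29 and fell in 1, with Cd63 at 1.68 and Lgmn at 1.12 (adjusted p = 1.1e-05; adjusted p = 0.346 with an estimated correlation). Efferocytosis receptors rose in 8 of 12 and fell in 3, with Mfge8 at 1.31 and Timd4 at 1.23 (adjusted p = 0.0468; adjusted p = 0.233 with an estimated correlation). Cell cycle genes fell in 14 of 29, with Cdc20 at -0.95 and Ccnb2 at -0.84 (median -0.35; adjusted p = 8.30e-06; adjusted p = 0.353 with an estimated correlation). No shift passed for MHC class I and cross-presentation (adjusted p = 0.106), MHC class II (0.521; median 0.084 and mean -0.098), or glycolysis and hypoxia (0.813). Nor did markers of macrophages (0.393), monocytes (0.352), pDC (0.521), NK cells (0.811), epithelium (0.815), endothelium (0.161) and fibroblasts (0.813; median 0.06, direction down) pass. Of 34 lists tested, 20 shifted up and 3 down by camera at the preset correlation, 23 at an unadjusted p under 0.05 and 25 by fry. By fry the immediate early and neutrophil lists lost the threshold. Gained were TLRs and adaptors, MHC class I and cross-presentation (adjusted p = 0.0422), pDC markers (0.00151, down, 1 of 6 past the gene test each way) and the 1 endothelial gene (0.0295, down). With estimated correlations 0 passed, the smallest adjusted p being 0.195.

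**Figure D3:**
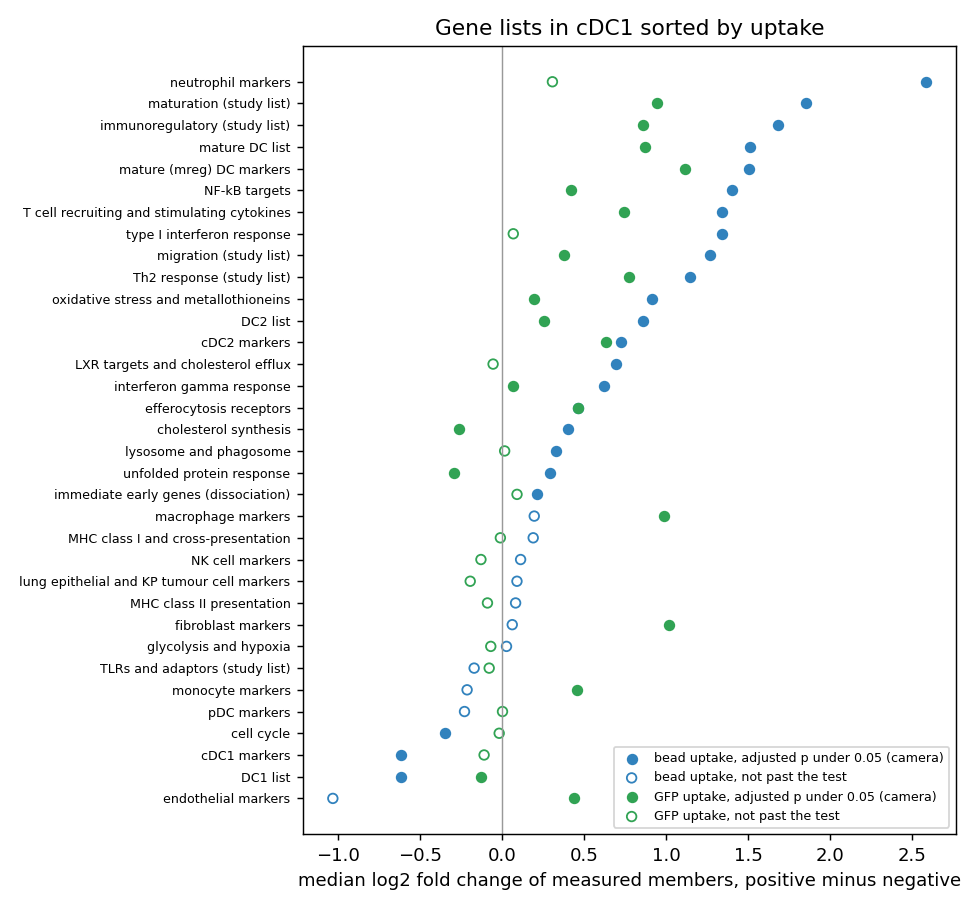
Median log2 change of each gene list with bead uptake (blue) and GFP uptake (green); filled points passed camera at the preset correlation, and with an estimated one 0 lists passed in either comparison. Neutrophil markers stood highest with beads at 2.58, the maturation study list at 1.85 with beads and 0.94 with GFP, macrophage markers at 0.985 with GFP, and the unfolded protein response list at 0.29 with beads and -0.29 with GFP.

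Whether cDC1 that carry tumor GFP differ in the same way was asked by comparing GFP-positive with GFP-negative cells from tumor-bearing lungs. The values are reads inferred from the deposited values by removing a divisor that no source records. No gene passed: limma called 0 of 11574, the smallest adjusted p being 0.0988, shared by 20 genes. Il12b was higher with GFP, 649 (SD 161) against 177 (SD 10.8), a log2 difference of 1.84 (SE 0.20, Benjamini-Hochberg adjusted p = 0.0988). Ccr7 was higher with 828 (SD 122) against 315 (SD 81.2), 1.41 (SE 0.19, adjusted p = 0.116), and Cd274 with 170 (SD 12.8) against 79.5 (SD 15.5), 1.1 (SE 0.14, adjusted p = 0.103). Also higher were Cd80 by 0.99 (SE 0.17, adjusted p = 0.191), Cd40 by 0.94 (SE 0.14, adjusted p = 0.129) and Pdcd1lg2 by 0.86 (SE 0.21, adjusted p = 0.366). Cd200 was higher by 0.67 (SE 0.13, adjusted p = 0.227), Axl by 0.51 (SE 0.09, adjusted p = 0.207) and Il4ra by 0.39 (SE 0.15, adjusted p = 0.596). Cd86 (0.12), Clec9a (0.13) and Xcr1 (-0.08) differed little, with adjusted p of 0.746, 0.746 and 0.790. At an unadjusted p under 0.05 limma gave 956 genes, 570 higher and 386 lower, against 578.7 expected by chance. edgeR called 0, DESeq2 233, and a fit that shares the variance of all 11 libraries 112. The count rested on single libraries. It was 438 (368 higher, 70 lower) without GFP-negative replicate 1 and 15, all higher, without GFP-negative replicate 2, where the lone GFP-negative sample is assumed to vary like the others. The groups did not overlap in 26.4% of genes, against 20% by chance for 3 against 2, and of these 1184 were higher and 1867 lower, the opposite balance. In simulated libraries of this depth, 42 of 100 genes changed by 1 on the log2 scale were found. All simulated genes had 1 common dispersion and the changed ones came from those with more reads, so the spread of single genes is lacking. Most changes of that size were thus missed even there, and the share missed in the real libraries is not known.

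As groups, the mature DC genes stood higher in GFP-positive cDC1. The mature DC list was higher in 92 of 95 genes (median log2 0.87), including Fscn1 at 1.86 (SE 0.19, limma adjusted p = 0.0988), Arl5c at 1.34 and Marcksl1 at 1.07 (camera adjusted p = 1.12e-59; adjusted p = 0.198 with an estimated correlation), and 82 of them passed when adjusted over the list alone. mreg markers were higher in 19 of 19 (median 1.11), with Socs2 at 1.3 and Cacnb3 at 1.26 (adjusted p = 2.20e-28; adjusted p = 0.198 with an estimated correlation), 19 when adjusted over the list alone. Of the study lists, which are not independent evidence, maturation was higher in 7 of 7 (adjusted p = 9.64e-10; adjusted p = 0.272 with an estimated correlation) and immunoregulatory in 7 of 7 (adjusted p = 1.05e-08; adjusted p = 0.198 with an estimated correlation). Migration was higher in 8 of 8 (adjusted p = 1.62e-06; adjusted p = 0.198 with an estimated correlation) and Th2 response in 6 of 6 (adjusted p = 7.68e-06; adjusted p = 0.198 with an estimated correlation). These held 6, 6, 3 and 4 genes passing when adjusted over the list alone. The DC1 list was lower in most members, with 25 of 94 higher (median -0.12; adjusted p = 0.000146; adjusted p = 0.435 with an estimated correlation). The DC2 list, which shares Gadd45b and other members with the mature DC list, was higher in 61 of 94, with Gadd45b at 1.07 (median 0.26; 0.16 with lists of 200 genes; adjusted p = 6.88e-05; adjusted p = 0.448 with an estimated correlation). cDC2 markers were higher in 10 of 12, with Cd209a at 1.44 and Zeb2 at 1.36 (adjusted p = 0.000171; adjusted p = 0.305 with an estimated correlation). T cell recruiting and stimulating cytokines were higher in 13 of 15, with Ccl22 at 1.31 and Ccl5 at 1.32 (adjusted p = 6.81e-11; adjusted p = 0.198 with an estimated correlation). NF-kB targets were higher in 17 of 18, with Tnf at 1.25 (adjusted p = 2.77e-11; adjusted p = 0.211 with an estimated correlation).

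Genes of macrophages and other cells stood higher in the same GFP-positive samples. Macrophage markers were higher in 16 of 18 (median 0.985), led by the complement genes C1qc at 3.14 (SE 0.61, limma adjusted p = 0.239), C1qb at 2.88 (SE 0.58, adjusted p = 0.249) and C1qa at 2.80 (SE 0.51, adjusted p = 0.207), with Mafb at 1.56 (camera adjusted p = 6.96e-08; adjusted p = 0.368 with an estimated correlation). Monocyte markers were higher in 9 of 13, with F13a1 at 2.24 and Cx3cr1 at 1.61 (adjusted p = 0.0226; adjusted p = 0.435 with an estimated correlation). Fibroblast markers were higher in 8 of 9, with Mgp at 0.99 (adjusted p = 0.0186; adjusted p = 0.603 with an estimated correlation), and endothelial markers in 9 of 10 (adjusted p = 0.0102; adjusted p = 0.532 with an estimated correlation). B cell markers were higher in 5 of 6 (adjusted p = 0.0108; adjusted p = 0.305 with an estimated correlation). Efferocytosis receptors were higher in 14 of 17, with Stab1 at 1.24 and Itgb5 at 1.05 (adjusted p = 0.00201; adjusted p = 0.198 with an estimated correlation). Oxidative stress genes were higher in 11 of 13, with Gclc at 0.85 (adjusted p = 0.00852; adjusted p = 0.368 with an estimated correlation), and interferon gamma response genes in 13 of 23, with Gbp5 at 1.36 (adjusted p = 0.0454; adjusted p = 0.712 with an estimated correlation). Lower were unfolded protein response genes, with 1 of 15 higher and Creld2 at -0.53 (adjusted p = 9.59e-05; adjusted p = 0.305 with an estimated correlation), and cholesterol synthesis genes, with 4 of 22 higher and Cyp51 at -0.46 (adjusted p = 0.000536; adjusted p = 0.435 with an estimated correlation).

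Of 38 lists, 18 shifted up and 3 down with GFP by camera at the preset correlation, 22 at an unadjusted p under 0.05 and 8 by fry. Those 8 were the mature DC list, mreg markers, the 4 study lists of maturation, immunoregulatory, migration and Th2 response genes, T cell recruiting and stimulating cytokines, and NF-kB targets. Without GFP-negative replicate 1, 13 lists passed. With estimated correlations 0 passed, the smallest adjusted p being 0.198. On the values as deposited, 2 lists passed, T cell recruiting and stimulating cytokines and mreg markers (both adjusted p = 0.0344). Type I interferon response genes did not pass, though Oasl1 read 1.06 and Isg15 0.54 (adjusted p = 0.0852), and neither did MHC class II (0.0714), cDC1 markers (0.160) and cell cycle genes (0.490). The other lists that did not pass were lysosome and phagosome (0.129), immediate early genes (0.180), glycolysis and hypoxia (0.814; median -0.07, mean 0.03, direction down) and LXR targets (0.772; median -0.05, mean 0.28, direction up). MHC class I and cross-presentation (0.999; median -0.01, mean 0.03, direction down) and TLRs and adaptors (0.673; median -0.08, mean 0.03, direction down) did not either. Nor did markers of T cells (0.615), NK cells (0.653), neutrophils (0.653), mast cells and basophils (0.490), pDC (0.408), epithelium (0.843) and red cells (0.117).

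Where the 2 kinds of uptake differ was tested directly, as the GFP effect minus the bead effect. Scd1 showed the largest gap, rising by 3.49 with beads and standing at 0.14 with GFP, a difference of -3.35 (SE 0.40, limma adjusted p = 0.000768). Smaller effects with GFP than with beads were also found for Cd69 (-2.70, SE 0.30, adjusted p = 0.00066), Lrrc32 (-2.67, SE 0.31, adjusted p = 0.00067) and Il12b (-2.55, SE 0.29, adjusted p = 0.00066). The same went for Optn (-2.48), Cxcl2 (-2.36, SE 0.38, adjusted p = 0.00435), Creb5 (-2.36), Gem (-2.31) and the antiviral genes Rsad2 (-2.29, SE 0.26, adjusted p = 0.00067) and Ifit3 (-2.11, SE 0.33, adjusted p = 0.00375). Higher with GFP relative to beads were Itgb5 (2.00, SE 0.32, adjusted p = 0.00384), an integrin that binds dying cells, Dusp7 (1.92), Dok2 (1.86, SE 0.22, adjusted p = 0.000768), Cd209a (1.76, SE 0.48, adjusted p = 0.048). The same held for Notch4 (1.56), Cxcr3 (1.54), Vwf (1.52), Alms1 (1.49), Ttc28 (1.45) and Dusp6 (1.38, SE 0.26, adjusted p = 0.00917). Of the fixed genes, Cd274 (-1.69, SE 0.19, adjusted p = 0.00066), Pdcd1lg2 (-1.61, SE 0.24, adjusted p = 0.00338), Cd80 (-1.33, SE 0.21, adjusted p = 0.00394), Cd86 (-1.03, SE 0.15, adjusted p = 0.00238) and Clec9a (0.78, SE 0.15, adjusted p = 0.00920) differed. Ccr7 did not (-0.44, SE 0.24, adjusted p = 0.312), nor did Cd40 (-0.78, adjusted p = 0.0624), Axl (-0.97, adjusted p = 0.0983), Xcr1 (0.35, adjusted p = 0.118), Cd200 (0.28, adjusted p = 0.337) and Il4ra (-0.31, adjusted p = 0.424). With the replicate number as a block, Cd40 (adjusted p = 0.0342) and Axl (adjusted p = 0.0121) passed and Alms1 (adjusted p = 0.0704) did not. With GFP values as deposited, the difference changed sign for Pdcd1lg2 (0.35), Cd80 (0.71), Cd209a (-0.86), Alms1 (-2.22) and Creb5 (1.96).

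In all, 626 of 9516 shared genes differed between the effects (6.58%), 175 higher and 451 lower with GFP. Of them, 450 were higher with beads and had a lower log2 change with GFP. Another 171 were lower with beads and had a higher log2 change with GFP, and 5 fell outside both. Neither count asked for the sign of the GFP effect, so genes that went the opposite way with GFP are included. At an unadjusted p under 0.05 there were 2127 against 475.8 expected by chance, and edgeR called 596 and DESeq2 950 (361 higher and 589 lower). The count and its split moved with single libraries, to 704 higher and 726 lower without GFP-negative replicate 1 and to 60 and 222 without GFP-positive replicate 2. They were 83 and 296 without GFP-positive replicate 3, 73 and 278 without bead-negative replicate 1, 66 and 268 without bead-negative replicate 2, and 71 and 253 without bead-positive replicate 3. With GFP values as deposited, 0 passed. Of the 2783 bead-changed genes listed in both experiments, 1980 (71.1%) had the same sign with GFP, against 61.0% of all shared genes, and the effects correlated across genes at r = 0.43 (Spearman 0.32). Il12b, Ccr7 and Cd274 were among those of the same sign. The bead and GFP cells also differ in tumor burden, in the time since uptake and in markers of other cells. The difference is thus between whole experiments.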

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

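Of the tests below, those on macrophage genes and on the mature DC genes in GFP-positive cDC1 were written before their results were seen. The tests on the splits of the bead libraries and on the GFP values were chosen only after the result was seen. So were those on the macrophage genes set against every DC class, the genes in a window around Ccr7 and the ribosomal genes.

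The difference between cDC1 with and without uptake was not the same for beads and for GFP in 626 of 9516 shared genes. The limma test was of the difference itself (adjusted p from 0.000354). The count moved with the processing. It was 282 without GFP-positive replicate 2, 950 by DESeq2 and 0 with GFP values as deposited. Scd1 (-3.35, SE 0.40, adjusted p = 0.000768), Lrrc32 (-2.67, SE 0.31, adjusted p = 0.00067) and Cd274 (-1.69, SE 0.19, adjusted p = 0.00066) were among the genes with a smaller GFP effect, and Itgb5 (2.00, SE 0.32, adjusted p = 0.00384) and Dok2 (1.86, SE 0.22, adjusted p = 0.000768) among those with a larger one. Ccr7 (-0.44, adjusted p = 0.312) did not pass. The time since uptake, tumor burden and the particle itself all differ between the experiments and were not tested apart. Markers of other cells differ too. Neutrophil markers rose in 9 of 9 with beads, while only 1 was measured with GFP. Macrophage markers were higher in 16 of 18 with GFP and in 8 of 12 with beads, where the list did not pass. How many of the 626 genes follow such cells was not tested.

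Among the 1874 barcodes that the authors left out, 62 carried a deposited pdc_filt_score above that of every passed cell, whose highest was 0.00937. They were high in genes of plasmacytoid DC. Siglech read 1639 CPM against 5.63 in passed cells, Ly6d 4327 against 2.54 and Ccr9 1267 against 4.92. Cox6a2 read 1496 against 2.80 and Klk1 956 against 0.126. The score used to pick them may rest on such genes, so these levels are no independent evidence of what these barcodes are. They had a median of 4727 UMIs, 54 of them 1000 or more, and 4, 46, 4 and 8 came from WT naive, WT tumor, KO naive and KO tumor. Most other left-out barcodes were shallow, 1757 of the 1874 lying under the lowest UMI count of a passed cell. Shares of DC in the report thus leave the high-score barcodes out, and their larger number in WT tumor rests on 1 library.

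The count of 2835 genes changed with beads was set against other splits of the 6 libraries. The splits are too few for a share under 0.05: 1 of 10 splits, the real one, gave as many, and the highest of the others gave 0. The other splits include the 3 that part all 3 numbered pairs as the real one does, and differ from it in mixing bead-positive with bead-negative cells.

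The deposited GFP values spread widely within a group, where libraries correlated at only 0.519 to 0.533 across genes. Low read depth was argued against, since the median SD of the most-read 10% of genes was 0.934 times that of the least-read 10% (2.18 against 2.33 on the log2 scale). A divisor taken from another row gave whole reads for 100% of genes, but with the rows of 1 library shuffled the same search still gave whole reads for 37.7% of sets where under 5% had been predicted, so that test leaves the question open. A test added afterwards moved the divisor by 1 row: the lowest correlation within a group was then 0.347, against 0.960 with the divisor in place and 0.519 as deposited. The divisor was worked out from these same values, and moving it brings in unrelated numbers, so the test could hardly come out otherwise. It gives the divisor no independent support, and a divisor from another row stays an inference. No biological explanation was tested for the spread of the deposited values, which lies within groups.

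Macrophage genes stood higher in GFP-positive cDC1 together with the mature DC genes. Of 60 measured genes at least 8 times higher in macrophages than in DC1 of the single cells, 58 (96.7%) were higher, with a median log2 of 0.60, and in 25 the groups did not overlap upward and in 1 downward. Of the 60, 8 are also in the mature DC list and 25 in the DC2 list. The 21 genes at least 8 times higher than in every DC class, none in the mature DC list, were higher in 21 of 21 (median 0.82), so macrophages mixed into the sort, or their free RNA, may explain them, although the gate required CD24 and CD103. Of the most abundant in macrophages, Apoe stood 2.92 higher, Ctsd 0.68, Lyz2 0.46 and Ctss 0.02, and DC1 also express Lyz2 (1234 CPM) and Ctss (820.5 CPM). The same admixture was argued against as the source of the mature DC genes, such as Ccr7, Fscn1 and Il12b, since the estimated macrophage share of 1.37% supplies 0.707% of their difference at the median, and 3.8% at the 90th percentile share of 7.37%. What stays open for the mature DC genes is uptake itself, or mature cDC1 retaining or meeting more tumor material, which these samples do not part.

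Genes stood apart between KO and WT if 1 class or more had log2 ratios of at least 1 in size in both states. The sign had to be the same. Such genes were more frequent within 25 Mb of Ccr7 on chromosome 11 than elsewhere (GRCm38.p6 positions). In a window of 25 Mb on either side, 7 of 161 tested genes stood apart (4.35%), against 8 elsewhere (0.227%). The most in any of 3526 other windows was 2, which puts this window at percentile 100. BC018473, St6galnac2, Sphk1, Cygb and Mettl23 lay together, 17.4 to 17.7 Mb from Ccr7, and Rpl38 and Rpl23a at 15.5 and -21.0 Mb. None of the 7 lay nearer to Ccr7 than Rpl38. The other windows were centred more than 25 Mb from Ccr7 or on other chromosomes. The test thus shows an excess in the window and does not place it at Ccr7. The share in the window was 19.2 times that elsewhere, which argues against a difference in library preparation as the source of the excess. DNA of another strain carried along with the targeted gene is a candidate explanation, and the window test cannot single it out. Ribosomal genes such as Rpl35, Rpl23a and Rpl38 were lower in KO, yet their median log2 ratio nearest 0 was -0.0252 and 51.7% were lower in both KO libraries, so a preparation difference and the loss of Ccr7 cannot be told apart for them, because genotype and library are the same split. The bound written against a preparation difference, a median near 0 in some class, was met. But the medians lay below 0 in every class and state while members go both ways, so the median decides nothing. That judgment was made after the value was seen. With ribosomal genes left out, 5 genes in the window and 4 elsewhere stood apart.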

How the results depend on the processing

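The main tests and 35 lists were fixed before the data were examined, 3 lists were drawn from the single cells, and several tests of explanations were chosen after, as said beside them; edgeR as an alternative, the pseudocounts, the low-value filter, log2 CPM for lists and the GFP values as deposited were chosen after, and the type I interferon and immediate early lists were picked for the single cells after their values were seen. The cause of the changes below was not tested. The bead count of 2835 stayed within 1.5 times in all 14 alternatives (leave-one-out 1973 to 2809), though its falls (1222) numbered 792 and 738 without bead-negative replicates 1 and 2 and 1838 with the replicate block. Class shares and the KO ratios of Ccr7 in mature DC stayed within 1.5 times, as did 200-gene lists except the DC2 list, whose median went from 0.86 to 0.46 with beads and from 0.26 to 0.16 with GFP. Tag differences kept their sign, and stayed within 1.5 times without any 1 library except CD11c of mature DC against DC1 (-0.14), at -0.042 without WT naive and -0.23 without KO tumor. On log2 counts per 1000 tags, which is another scale, it was -1.89. Smaller there were APC of mature DC against DC2 (0.24 in place of 0.81), CD11b of mature DC against DC1 (0.51 in place of 1.5), I.A.I.E of mature DC against DC2 (0.44 in place of 1.06) and CD11c of DC1 against DC2 (-0.12 in place of -0.53). I.A.I.E of mature DC against DC1 (1.66 in place of 2.36) and of DC1 against DC2 (-1.23 in place of -1.30) were smaller too. So was PE of mature DC against DC2 (0.63 in place of 0.92), and the remaining differences were larger. Centred log-ratios are in natural logs, so sizes on the 2 scales are not in like units. For GFP uptake (0 genes by limma and edgeR, 956 at an unadjusted p under 0.05), DESeq2 gave 233 genes, all 11 libraries in 1 fit 112 and leave-one-out 0 to 438, with 438 without GFP-negative replicate 1 and 15 without GFP-negative replicate 2, where the lone GFP-negative sample is assumed to vary like the others. For the difference (626), DESeq2 gave 950, GFP values as deposited 0, and leave-one-out 282 to 1430: 351 and 334 without bead-negative replicates 1 and 2, 324 without bead-positive replicate 3, 1430 without GFP-negative replicate 1, and 282 and 379 without GFP-positive replicates 2 and 3. Its genes higher with GFP (175) ranged from 60 to 704 and those lower (451) from 222 to 726. With deposited GFP values the difference changed sign for Cd209a (-0.86), Alms1 (-2.22), Creb5 (1.96), Pdcd1lg2 (0.35) and Cd80 (0.71). Beyond these, 56 values of named genes in the difference lost the threshold and 8 gained it; with beads 21 lost and 7 gained it, and with GFP 127 gained it. Lists past the threshold with an estimated correlation numbered 0 for beads and 0 for GFP, against 23 and 21; for GFP also 8 by fry, 2 on deposited values and 13 to 28 leave-one-out, with 13 without GFP-negative replicate 1. With the replicate block as pairing, 3942 genes changed with beads, 6 with GFP (C1qa, C1qb, C1qc, Apoe and F13a1 among them) and 648 in the difference, and 24 and 25 lists passed; besides the TLR list, calls changed for Cd300c, Bst2 and Gsn with beads, Alms1, Cd40 and Axl in the difference, and for no other named bead gene or list. With GFP the block lost interferon gamma genes (adjusted p = 0.0507) and gained type I interferon (0.0290), lysosome (0.0249), immediate early (0.0367), epithelial (0.000116, down) and red cell genes (0.0249, down). In GFP the same-numbered pairs correlated at 0.341 and 0.183, too few pairs to decide. In single cells the type I interferon median moved in DC2 of WT to 1.49 with 1 CPM added and 0.71 at a 20 CPM minimum, and in mature DC of KO to -0.013 at 20 CPM, a change of sign. The immediate early median moved to -0.79 in DC2 of KO and -0.51 in mature DC of KO at 20 CPM, and to -0.38 in mature DC of WT with TMM factors. Of the named single-cell values under all alternatives, 150 moved and 922 did not for tumor against naive, and 35 and 591 for KO against WT. At a 20 CPM minimum the same rule named 17 of 20 genes again in DC1, 19 of 20 in DC2 and 16 of 20 in mature DC for the tumor, and 14 of 16, 10 of 20 and 13 of 20 for KO. The planned run without a filter on low counts was not run, since the deposited lists were already filtered.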

Other observations

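Surface tags parted the mature DC into DC1-like and DC2-like cells, and the former were a smaller share in the tumor libraries. By the PE and CD11b tags, 62.4% (53.0–71.2) of mature DC were DC1-like in WT naive and 25.6% (20.8–30.7) in WT tumor, and 60.4% (52.9–67.6) and 17.9% (13–23.8) in KO naive and KO tumor. Their number was 73 and 81 in WT, and 110 and 38 in KO. Il12b was mainly in the DC1-like cells, at 1236 CPM in WT naive, 686 in WT tumor, 1367 in KO naive and 1922 in KO tumor, against 42.8, 148, 220.3 and 149 in the DC2-like. Pdcd1lg2 was higher with a tumor in both kinds, at 45.5 CPM in WT naive and 167 in WT tumor among DC1-like cells and 11.7 (2.41–34.1; 3 UMIs) and 128 among DC2-like cells. Ccl22 was lower with a tumor in both kinds, with log2 ratios of -1.17 and -0.75 in DC1-like and -0.49 and -0.41 in DC2-like cells of WT and KO. These genes were chosen after their values were seen.

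The tests that follow, on the tag mixture and on Il12b in DC1-like cells, were written before their results were seen.

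Mature DC lay between DC1 and DC2 in their mean CD11b, PE and APC tags, though above both in the MHC class II tag. CD11c was below DC2 relative to the other tags, and against DC1 it was higher in 1 of 4 libraries. For the CD11b and PE tags, which were the ones tested, a mixture of 2 kinds of cells may explain the intermediate means. In the middle of 3 equal parts between the DC1 and DC2 medians lay 11.1, 12, 17.6 and 6.60% of mature DC in WT naive, WT tumor, KO naive and KO tumor, so the highest was 17.6%, under the 20% set beforehand for a mixture and far from the 50% set for a single intermediate kind. For comparison, 96.0% or more of DC1 and 1.06 to 4.50% of DC2 counted as DC1-like. In the same middle part and library order lay 7.89, 5.79, 6.89 and 6.92% of DC1 and 3.66, 4.24, 4.35 and 3.06% of DC2. Mature DC held more such cells than either class except in KO tumor, so some intermediate cells beside a mixture are not excluded. The tags say nothing about which kind a mature cell came from, since maturation could change them.

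Il12b stood lower in mature DC with a tumor, and a lower share of DC1-like cells is a candidate explanation in both genotypes. In WT naive Il12b stood at 1236 CPM in DC1-like cells and 42.8 in DC2-like cells (11 UMIs). The DC1-like share was 62.4% in WT naive and 25.6% in WT tumor, which by itself would lower Il12b in the class. How much of the fall it supplies was not computed. Among DC1-like mature DC the log2 ratio of tumor over naive was -0.84 in WT and 0.49 in KO, the latter being the nearer to 0, so neither bound set beforehand was met in both genotypes and the question stays open. A lower level per DC1-like cell in WT remains possible and rests on 1 library per state.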
